A study of Mus musculus with 2 samples.

How the data were processed

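Nuclei from cerebrum of 5xFAD mice were isolated by gradient centrifugation and pooled from 3 animals per genotype, and libraries were made with the PIPseq T20 3' kit, version 4.0, per the labels' protocols. Each genotype, Loxp_5xFAD and mKO_5xFAD, had 1 library. The deposited matrices hold whole-number counts per gene and barcode for 32227 genes, not normalized. The GRCm39 build and Seurat 4.1.4 are named in the submitters' processing notes, with no role given; the aligner, the counting, the calling of barcodes and any filter are not given in the sources used here. Whether a count is a molecule or a read is not stated, so values are called counts. The files pair gene symbols with identifiers. Of the listed symbols 3 were matched under another name, and 5 were not used here.

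From the deposited counts, nuclei with at least 500 detected genes and at most 5% mitochondrial counts were kept. Doublets were scored per library with scrublet as run by scanpy 1.11.5, at an expected rate of 6%. Its own threshold marked 4 barcodes per library, so a score of 0.25, set after the score histograms were seen, was used and removed 631 barcodes (3.18%) and 569 (3.41%). This left 19201 and 16103 nuclei. Counts were scaled to 10000 per nucleus and log-transformed, 3000 variable genes gave 30 principal components, and leiden clustering (leidenalg 0.10.2, resolution 1, 15 neighbours) was run on both libraries together without integration. Of 62 clusters, 49 were named from marker genes fixed before the data were examined and fell into 12 classes; 13 stayed unnamed. A named cluster had at least 3 markers up and led the next class of its lineage by 0.5 on the log2 scale. Against other lineages its class needed only the highest score among classes with at least 3 markers up. No cluster with more leading markers of another class than of its own was named. Clusters outside neurons also needed a marker of their class among their 10 leading genes. These naming rules were set after the clusters were seen, so shares rest on rebuilt names. In most glia-like clusters markers of another lineage were also up.

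Counts were summed per library and class and divided by the class total to give CPM. Ratios are log2 of mKO over control CPM with 0.5 added to both counts, and with 0.1 CPM added where clusters were weighted alike. Single genes have exact conditional binomial intervals, counts exact Poisson intervals and shares exact Clopper-Pearson binomial intervals, all at 95% and for counting error only; a count of 0 was set to 3 counts for a bound. A list is described by the median over members with at least 5 CPM in 1 library or the other, an order-statistic interval over members, which are not independent, and its place among 10000 random lists of the same size matched on mean expression in 20 bins. The 25 lists and 60 ligand-receptor pairs were fixed before the data were examined, as were the marker genes, the rule for named genes and 11 alternatives.

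The rule named genes with at least 20 CPM and 30 counts in a class, at no less than 0.2 times the highest class, leaving out mitochondrial, ribosomal, sex-linked and unnamed model genes, ranked by the interval bound nearest 0. It took 12 genes per side in microglia-like nuclei, 6 per side in 5 further classes, and 3 per side in other classes with at least 200 nuclei in each library. It also took up to 4 members of each list whose intervals lay farthest from 0. Some of the genes it took are not reported here.

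Another 11 alternatives were added after the data were seen. A ratio relative to a class's own markers used members specific to the class and left the members of the list out of the markers it was set against. A version against all of the class's markers, apart from the gene itself, was added. Specific was first taken as at least 3 times the highest class of every other lineage, which left the interferon-stimulated list with 1 member and no value. It was then taken as at least 3 times the highest class of the neuron, astrocyte and oligodendrocyte lineages, which left 8 members and gave the values printed; both definitions are among the alternatives. TMM factors came from edgeR 4.0.16 in R 4.3.3. Gene order was taken from a mouse annotation of another build, GRCm38, and used only for which genes neighbour each other. Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.

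The intervals and percentiles were run on simulated data drawn from the class sums, with 200 genes altered by known folds. Counts were independent Poisson draws from 1 pooled profile per class, the model that the intervals assume, so coverage near 95% was set by the design. Variation between mice or nuclei, mixed RNA and a shared shift of glial genes were not simulated. In microglia-like nuclei 96.1% of intervals over 12049 genes held the true ratio, and of genes altered 1.5-, 2- and 4-fold 73.1%, 88.1% and 95.5% had an interval beyond 0 on the right side. In excitatory neuron-like nuclei 95.4% of intervals over 10653 genes held the truth and 100% of altered genes were recovered at each fold. Of 40 unchanged lists of 25 genes, 4 and 2 lay outside the central 95% of random lists. The control library held 256460513 counts and the mKO library 206981922; in microglia-like nuclei this depth left a gene such as Cgas with 37 and 10 counts.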

Results

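Single-nucleus RNA sequencing was done on cerebrum from 5xFAD mice, a transgenic line that deposits amyloid in the brain. Loxp_5xFAD was the control genotype, and mKO_5xFAD was labelled as lacking cGAS in microglia; tamoxifen was given at 2 months of age. cGAS is a sensor of cytosolic DNA whose product activates STING and, through it, interferon-stimulated genes. Nuclei of 3 mice aged 7 months were pooled per genotype, giving 1 library per group. The control library held 256460513 counts over 19833 barcodes, with a median of 11525 per barcode. The mKO library held 206981922 counts over 16672 barcodes, with a median of 10440. With 1 library per group no difference had a replicate check, so no test was run and no p-value is given. Intervals cover counting error only, and each ratio is mKO over control on the log2 scale. Uty and the other Y-linked genes were abundant in both libraries (Uty, 33559 and 25962 counts), while Xist gave 106 and 108 counts. The sex-linked list had a median log2 ratio of -0.08 over 4 measured members, with 1 above 0 and 3 below.

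The first comparison asked how far Cgas, the targeted gene, differed between the libraries. In microglia-like nuclei Cgas gave 37 counts in the control library (6.80 CPM, exact Poisson interval 4.79 to 9.38) and 10 counts in the mKO library (4.05 CPM, 1.94 to 7.45). The log2 ratio was -0.70 with an exact interval of -1.92 to 0.29, so a difference was not detectable at this depth. Excitatory neuron-like nuclei gave 107 and 104 counts (1.10 and 1.28 CPM), and inhibitory interneuron-like nuclei gave 70 and 51. Over all kept nuclei Cgas gave 350 and 264 counts, with a log2 ratio of -0.10 (-0.33 to 0.14). The deleted part of the gene is not given in the labels, and counts from a 3' kit check the deletion only if that part holds the counted end.

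The second comparison concerned the makeup of the tissue. In the clusters as named, glia-like nuclei took a smaller share of the mKO library than of the control library, by an amount that varied with the clustering. Microglia-like nuclei were 2.42% of the control library (465 nuclei, exact binomial interval 2.21 to 2.65) and 1.23% of the mKO library (198 nuclei, 1.07 to 1.41), a log2 ratio of -0.98 (-1.23 to -0.73). Oligodendrocyte-like nuclei, the myelin-forming class, numbered 712 and 10 (3.71% and 0.0621%), and oligodendrocyte precursor-like nuclei 533 and 56 (2.78% and 0.348%). Another 7 clusters were closest to oligodendrocytes by the markers but stayed unnamed, most of them with markers of another lineage up, and held 2022 and 1980 nuclei. With these the oligodendrocyte-like shares were 14.2% and 12.4%, and the log2 ratio went from -5.83 to -0.20 (-0.29 to -0.12). This rests on cluster 3, which held 907 and 1178 of these nuclei and had microglia markers among its leading genes. Without it the ratio was -0.92 (-1.04 to -0.80). The ratio was -0.14 with at least 1000 genes and at most 1% mitochondrial counts per nucleus, and -0.17 with the libraries clustered separately. Astrocyte-like nuclei were 1.52% and 0.764%, and fibroblast-like nuclei of meninges and vessels 1.33% and 0.447%. Cortical and hippocampal excitatory neuron-like nuclei were 36.9% and 43.2%, and inhibitory interneuron-like nuclei 26.1% and 28.2%. In the interneuron-like class, cluster 0 held 2342 and 2269 nuclei, with 6 of 15 class markers up. None of these markers was among its 10 leading genes, so the class may hold neurons other than interneurons. Other excitatory neuron-like nuclei were 3.80% and 4.65%, striatal projection neuron-like nuclei 5.09% and 4.14%, and dentate granule neuron-like nuclei 1.95% and 1.55%. Endothelial-like nuclei were 0.937% and 0.894%, and choroid plexus-like nuclei 0.214% and 0.137%. Unnamed clusters held 13.2% and 14.3%.

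The lowest total count of a barcode was 2580 in the control library and 5770 in the mKO library, and 15.9% of the control barcodes lay under 5770. With only barcodes of at least 5770 counts, the log2 ratio of the microglia-like share was -0.61 (-0.88 to -0.35), that of oligodendrocyte-like nuclei -2.24 (-3.44 to -1.30) and that of precursor-like nuclei -1.54 (-2.01 to -1.10). Astrocyte-like nuclei then stood at 0.31 (-0.08 to 0.71), endothelial-like nuclei at 1.23 (0.80 to 1.69) and fibroblast-like nuclei at 0.70 (0.15 to 1.28). The oligodendrocyte-like value at that total varied with the clustering. It was 0.01 (-0.08 to 0.10) with the closest unnamed clusters and 0.17 (0.07 to 0.26) under the stricter filter on nuclei. Without doublet removal it was -0.52, and at leiden resolution 0.5 it was -0.46. With the libraries clustered separately it was 2.81 (2.48 to 3.17), from 80 control and 565 mKO nuclei. Under that clustering, without the limit on counts, the myelin list of oligodendrocyte-like nuclei stood at -2.64. The nuclei so named thus differed in myelin RNA between the libraries, and the 2.81 cannot be read as a higher share of like nuclei. The microglia-like share also turned to 0.24 (0.14 to 0.35) when 2 unnamed clusters with at least 3 microglia markers among their 10 leading genes were added. These were cluster 51, with 44 and 30 nuclei, and cluster 3, which was also counted above among those closest to oligodendrocytes. Cluster 3 had microglia markers at 1190 CPM in the control and 1046 CPM in the mKO library. Its median totals were 24790 and 18927.5 counts per barcode. Both 14 of 15 oligodendrocyte markers and 17 microglia markers were up in it, so the turn in sign cannot be read as a count of microglia. At leiden resolution 0.5 the microglia-like share was 0.26. With the libraries clustered separately no mKO cluster was named microglia-like, so no microglia result had a value there.

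**Figure D1:**
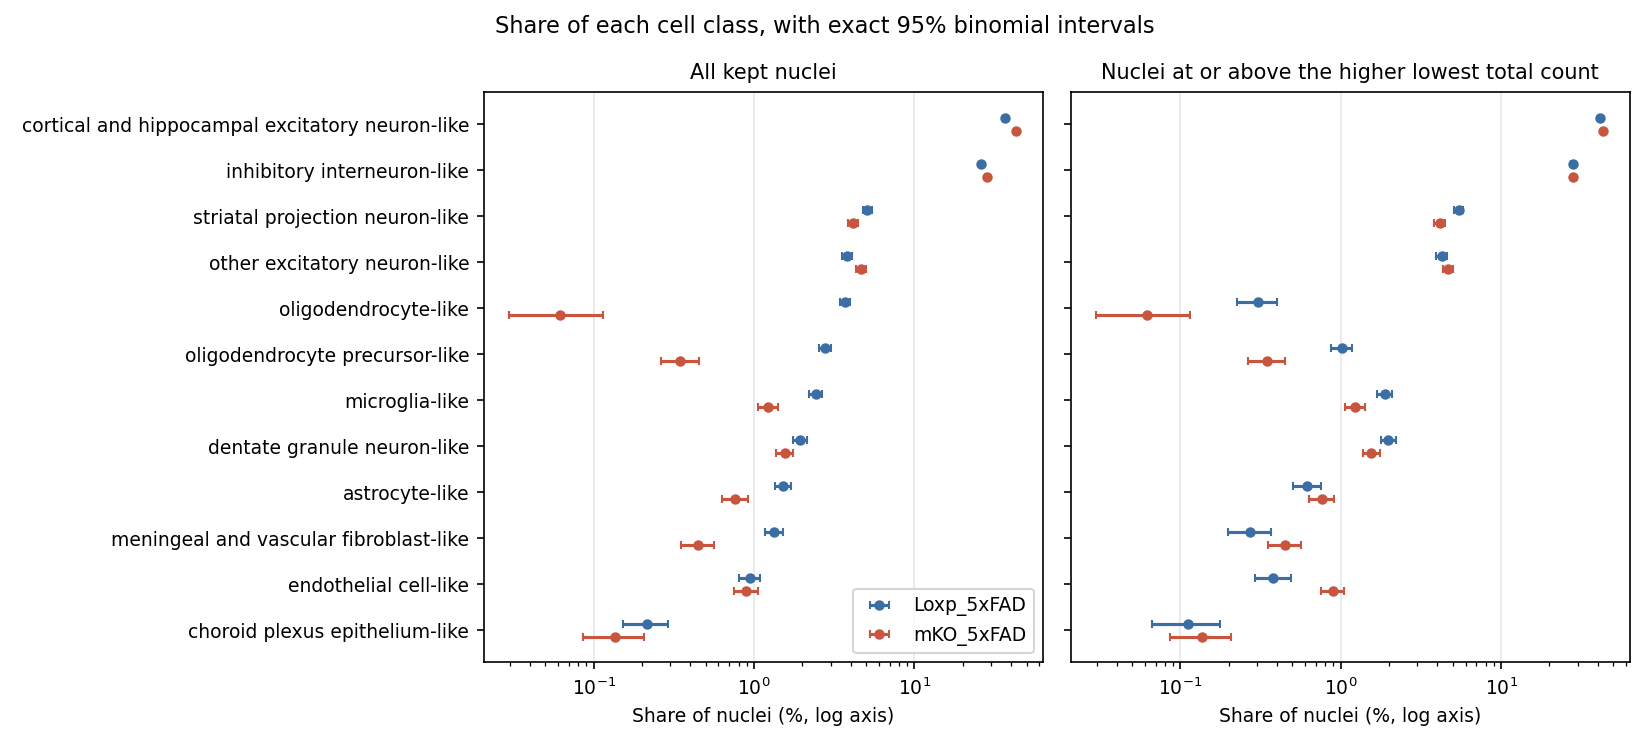
Share of nuclei in each named class, unnamed clusters left out (percent of kept nuclei, log axis) in Loxp_5xFAD (blue) and mKO_5xFAD (red), 1 library each, with exact 95% binomial intervals as bars. Oligodendrocyte-like nuclei were 3.71% and 0.0621% of all kept nuclei on the left, and 0.305% and 0.0621% on the right, where only barcodes with at least 5770 counts were used.

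The third comparison asked how innate immune and state genes of microglia-like nuclei differed. Interferon-stimulated genes were lower in the mKO library, with a median log2 ratio of -0.70 over 31 measured members (-0.94 to -0.49), 28 below 0 and 3 above. Sp100, a nuclear body protein, gave 111 and 17 counts (-1.53; -2.40 to -0.82), Slfn8 gave 78 and 12 (-1.51; -2.57 to -0.68), Sp110 gave 95 and 19 (-1.15; -1.98 to -0.46) and Oasl2 gave 34 and 4 (-1.80; -3.90 to -0.46). The cGAS-STING pathway list had a median of -0.59 over 14 members (-0.92 to -0.08), 13 of them below 0. In cluster 23 alone it stood at -0.27 (-0.68 to 0.14), with 6 members above 0 and 7 below, and with at least 5770 counts per barcode at -0.30. It had 2 members specific to microglia, too few for a value relative to the markers. Ifi204, a DNA sensor of the PYHIN family, gave 56 and 4 counts (-2.51; -4.59 to -1.23), and Sting1, the adaptor downstream of cGAS, gave 48 and 9 (-1.21; -2.49 to -0.23). Samhd1, a nucleotide hydrolase, stood at -0.74 (-1.19 to -0.33), and Irf3, the transcription factor that STING signalling activates, at -0.68 (-1.23 to -0.19). Random lists matched on expression had medians from -0.23 to 0.15 for the interferon-stimulated list and from -0.28 to 0.21 for the pathway list, as the central 95% of 10000 draws. These lists were drawn from all genes measured in the nuclei, not from microglial genes, whose markers were lower too, as given below. A place below the band thus does not set a list apart from that lower marker level.

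The microglia markers themselves were lower in the mKO microglia-like nuclei, with a median of -0.47 over 22 markers specific to the class (-0.52 to -0.20). Of all kept nuclei, 42 in the control library and 0 in the mKO library had at least 150 microglia marker counts per 10000. The highest values were 312 and 129. Those 42 had a median total of 3405 counts, under the lowest mKO total of 5770. Clusters 39 and 53, where microglia markers reached 8454 and 9822 CPM in the control library, held 133 and 64 control nuclei against 13 and 9 mKO nuclei. Cluster 23 held 268 and 176 nuclei with markers at 2468 and 2578 CPM, so most mKO microglia-like nuclei came from the cluster with the lower marker level. Markers of other classes also differed in these nuclei. Oligodendrocyte markers were at 3040 CPM in the control and 1598 CPM in the mKO library, astrocyte markers at 1151 and 899 CPM, dentate granule neuron markers at 1087 and 862 CPM and excitatory neuron markers at 2149 and 2368 CPM. Relative to the 22 microglia markers, none of which was in the list, the 8 interferon-stimulated members specific to the class had a median of -0.57 (-1.06 to -0.02), all 8 below 0. In cluster 23 alone the list stood at -0.24 over 28 members, 20 of them below 0. In the unnamed cluster 51 it stood at 1.00 over 32 members, 25 of them above 0.

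Homeostatic microglia genes had a median log2 ratio of -0.30 over 25 members (-0.36 to -0.16), with 19 below 0. Cx3cr1, the fractalkine receptor, stood at -0.78 (-1.06 to -0.52), Entpd1 at -0.77 (-0.97 to -0.58), Selplg at -0.55 and Tgfbr1 at -0.52. Phagocytosis and lysosome genes had a median of -0.39 over 26 members (-0.58 to -0.23), 25 below 0, among them Abca1 (-0.70), Dock2 (-0.69), Plcg2 (-0.68) and Inpp5d (-0.48). Inflammatory cytokine and NF-kB genes had a median of -0.48 over 16 members (-0.72 to -0.06), 13 below 0. Tnfaip3, an inhibitor of NF-kB, gave 45 and 5 counts (-1.91; -3.72 to -0.70), Il18 stood at -0.89, Tlr4 at -0.91 and Tlr7 at -0.45. Relative to the microglia markers outside each list these 3 lists stood at 0.15, 0.04 and 0.05, and in cluster 23 alone at 0.12, 0.07 and -0.01.

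Disease-associated microglia genes, which amyloid-associated microglia express more, had a median of -0.16 over 33 members (-0.46 to 0.03), with 12 above 0 and 21 below. Cybb, an oxidase subunit, gave 40 and 7 counts (-1.29), Lilrb4a stood at -0.72, Myo1e at -0.66 and Arhgap24 at -0.50. In cluster 23 the median of the list was 0.20, with 24 of 32 members above 0, and relative to the markers outside the list it was 0.32 (-0.24 to 0.75). Complement genes had a median of -0.21 over 10 members (-0.90 to 0.03), 7 below 0, with Itgb2 at -1.18, C4b at -0.90 and Itgam at -0.53, and stood at 0.08 in cluster 23. Antigen presentation genes had a median of -0.27 over 9 members (-0.64 to 0.21), 6 below 0, with Psmb10, a proteasome subunit, at 1.54 (12 and 16 counts) and Erap1 at -0.68. That list stood at 0.25 in cluster 23. DNA damage and senescence genes had a median of -0.14 over 11 members (-0.36 to 0.13), 6 below 0, and no member had an interval beyond 0.

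**Figure D2:**
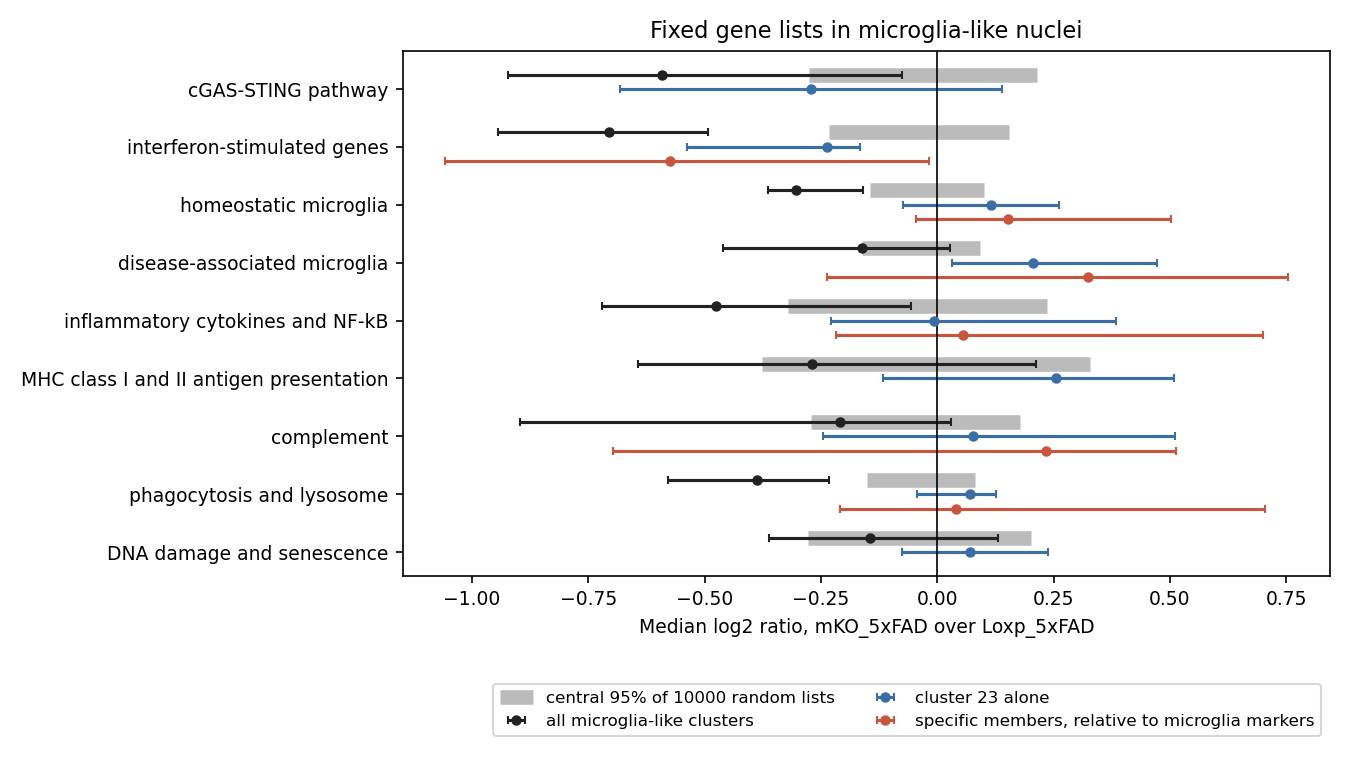
Median log2 ratio (mKO_5xFAD over Loxp_5xFAD) of fixed gene lists in microglia-like nuclei: all clusters (black), cluster 23 alone (blue) and members specific to microglia relative to the microglia markers outside the list (red, where at least 3 members were specific). Bars are order-statistic intervals over members, and grey bands hold the central 95% of 10000 random lists. The random lists were drawn from all genes measured in the nuclei, not from microglial genes alone. The interferon-stimulated list stood at -0.70, -0.24 and -0.57.

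Among the genes named by the fixed rule of size in microglia-like nuclei, Blnk, a B-cell and myeloid adaptor, gave 618 and 143 counts (-0.97; -1.24 to -0.71), and Spi1, a lineage transcription factor of myeloid cells, gave 172 and 33 (-1.22; -1.83 to -0.70). Cd84 stood at -0.91, Gvin1, an interferon-inducible GTPase, at -1.11, Rassf2 at -1.07, Amz1 at -1.41, Dock1 at -0.87, Fbn2 at -1.35 and Nr4a3 at -1.30. Blnk, Spi1, Cd84 and Gvin1 lay below 0 in all 3 microglia-like clusters and were specific to the class, while Dock1 and Nr4a3 lay below 0 in 1 of the 3 clusters. With at least 5770 counts per barcode Blnk stood at -0.60, Spi1 at -0.69, Cd84 at -0.48, Rassf2 at -0.56 and Dock1 at -0.29. Piezo2, a mechanically gated ion channel that was not specific to microglia, stood at -4.56 (-5.42 to -3.90). Gh, the pituitary growth hormone, gave 232 counts in control and 0 in mKO microglia-like nuclei, a log2 ratio of -5.13 or lower with 3 counts set as the floor. The genes that were higher by the rule were Tacr1 (1.67), Syt9 (1.28), Nptx2 (1.31), Sorbs2os (1.23), Trpc7 (1.19), Iqcj (0.81), Plk5 (1.06), Ajm1 (1.14), Usp5 (1.00), Slc5a6 (1.04), Dis3 (1.11) and Cadps2 (0.66). None of these 12 was specific to microglia-like nuclei. Among specific genes, ranked relative to the markers by a choice made after the values were seen, Olfml3 stood at 0.62 (0.06 to 1.15), Dkk2 at 0.38 and Ctsd at 0.00. Relative to the markers they were 1.09, 0.85 and 0.47, and with at least 5770 counts per barcode 1.04, 0.71 and 0.39.

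The fourth comparison asked whether synaptic and plasticity genes of neurons differed. They lay near 0. In excitatory neuron-like nuclei the excitatory synapse list had a median log2 ratio of -0.01 over 37 members (-0.03 to 0.01), 16 above 0 and 21 below, with Nlgn3 at 0.18, Nrxn2 at 0.17 and Dlg4 at 0.16. Presynaptic release genes had a median of 0.01 over 26 members (-0.03 to 0.07), 14 above 0, with Syt2 at 0.33, Slc17a7 at 0.23, Syp at 0.19 and Syt7 at 0.13. Genes linked to MEF2C, a transcription factor of neuronal plasticity, had a median of -0.02 over 20 members (-0.03 to -0.01), 16 below 0. Ntrk2, the receptor of BDNF, stood at 0.17, Kcnq5 and Pcdh17 at -0.11 and Rbfox1 at -0.04. In inhibitory interneuron-like nuclei GABA signalling genes had a median of 0.00 over 20 members (-0.04 to 0.07), 10 above and 10 below, with Slc32a1, the vesicular GABA transporter, at 0.28, Erbb4 at -0.15 and Gabrg3 at -0.13. With TMM factors the excitatory synapse, presynaptic and MEF2C-linked medians were -0.06, -0.04 and -0.07.

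Immediate early genes, which neuronal activity induces, were lower in mKO excitatory neuron-like nuclei, with a median of -0.24 over 12 members (-0.34 to -0.04) and 11 below 0. Nr4a3 stood at -0.42 (-0.48 to -0.35), Egr1 at -0.41 (-0.53 to -0.30), Nr4a2 at -0.34 and Arc at -0.32. Random lists had medians from -0.05 to 0.11. Heat shock and dissociation stress genes were lower in the same nuclei, with a median of -0.15 over 10 members (-0.23 to 0.01), 8 below 0. Amyloid precursor and processing genes had a median of 0.05 over 17 members (-0.01 to 0.09), 12 above 0, with Thy1 at 0.33, Psenen, a gamma-secretase subunit, at 0.30, Sorl1 at 0.10 and Ide, a protease that degrades amyloid peptide, at -0.09. Over all kept nuclei, nuclear-encoded oxidative phosphorylation genes had a median of 0.09 over 28 members (0.04 to 0.16), 22 above 0, with Ndufb9 at 0.28, Ndufa1 at 0.25 and Cox5b and Cox6c at 0.22. Over all kept nuclei the heat shock and dissociation stress list had a median of -0.10 over 10 members (-0.19 to 0.01), 8 below 0, with Hsp90ab1 at -0.21, Hsph1 at -0.19, Hspe1 at -0.16 and Hspa5, the chaperone of the endoplasmic reticulum, at 0.50.

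Piezo2 and Atp7b had the largest ratios among the genes named in excitatory and in inhibitory neuron-like nuclei, with the same sign in every neuron-like class. Piezo2 was at 157 CPM in control and 5.41 CPM in mKO excitatory neuron-like nuclei (-4.86; -5.00 to -4.73), at -3.96 in inhibitory, -3.94 in other excitatory, -5.39 in striatal and -5.40 in dentate granule neuron-like nuclei. Atp7b, a copper-transporting ATPase, was at 2.23 and 20.5 CPM in excitatory neuron-like nuclei (3.20; 3.00 to 3.41) and stood at 2.38 in inhibitory, 2.83 in other excitatory and 3.44 in dentate granule neuron-like nuclei. Trim30a, a member of the interferon-stimulated list, stood at 1.11 and 1.16 in excitatory and inhibitory neuron-like nuclei. In the same classes Kcnq1 stood at 0.95 and 0.86, Sorbs2os at 0.94 and 1.14, and Nrg3os at 0.64 and 0.76. The last 2 are antisense transcripts, whose counts could include the opposite strand since the use of strand in counting is not given in the sources used here. Aif1l stood at -0.45 and -0.51 and Il27 at -0.40 in both classes. Zfp951 (0.63), Npsr1 (-0.64), Tshz2 (-0.42) and Nr4a3 completed the genes named in excitatory neuron-like nuclei, and Scg2 (0.51), Foxp2 (-0.38), Nek10 (-0.45) and Sox2ot (-0.32) those in inhibitory interneuron-like nuclei. Foxp2, Tshz2 and Sox2ot stood at -0.08, -0.15 and -0.15 with the clusters of their class weighted alike, and Foxp2 lay below 0 in 4 of 13 clusters.

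In the smaller neuron-like classes, Fhod3 (1.45) and Slc5a6 (1.74) were higher and Fbn2 (-1.10) and Kcnc4 (-0.83) lower in mKO dentate granule neuron-like nuclei. Tmem178 (1.40), Thsd7b (1.14) and Kcnk10 (1.15) were higher and Aif1l (-0.62) and Mtpn (-0.80) lower in striatal projection neuron-like nuclei, where Tmem178 and Kcnk10 stood at 0.65 and 0.70 with clusters weighted alike. In other excitatory neuron-like nuclei Kcnq1 (1.09) and Sorbs2os (1.07) were higher and Npsr1 (-0.98) and Ttn (-0.82) lower.

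**Figure D3:**
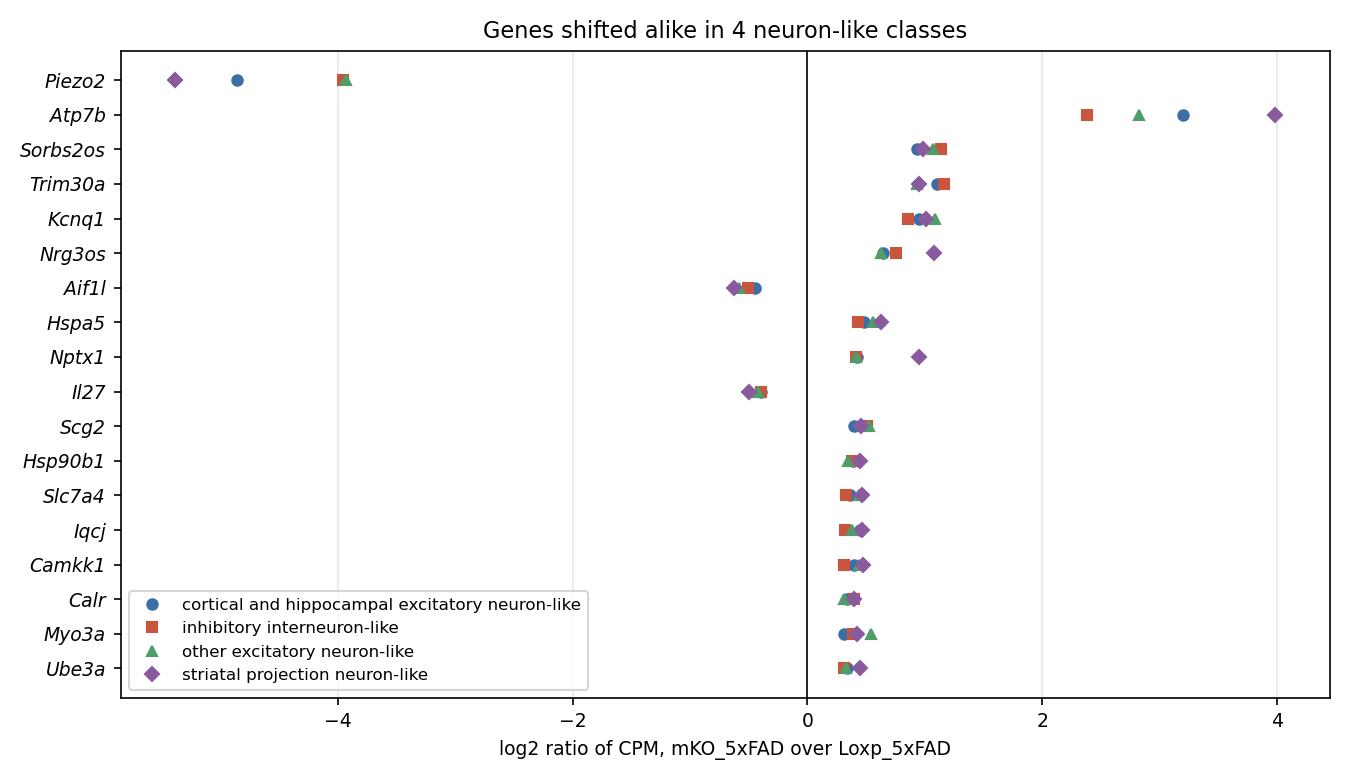
Log2 ratio of CPM (mKO_5xFAD over Loxp_5xFAD, 1 library each) in 4 neuron-like classes for named genes with a ratio of at least 0.3 in size and 1 sign in all 4; each point is 1 class. Piezo2 lay between -5.39 and -3.94, and Atp7b between 2.38 and 3.98; the set was chosen after values were seen.

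The fifth comparison concerned astrocytes, oligodendrocytes and vessels. Reactive astrocyte genes were lower in mKO astrocyte-like nuclei, with a median of -1.11 over 18 members (-1.83 to -0.70), 16 below 0. Gfap, the intermediate filament of reactive astrocytes, gave 97 and 15 counts (-2.16; -3.10 to -1.41), Aqp4 stood at -1.59, Apoe at -1.12, and Myoc gave 51 counts and 1 (-4.61; -10.52 to -2.64). Genes of glutamate, potassium and junctional handling had a median of -1.17, all 19 below 0, with Slc7a11 at -1.41, Glul at -1.32, Gpc5 at -1.27 and Slc1a2 at -1.21. Cholesterol synthesis genes had a median of -0.47 over 18 members, 15 below 0, but of -0.08 with clusters weighted alike and -0.20 with at least 5770 counts per barcode, with Cyp51 at -0.71, Msmo1 at -0.69 and Srebf2 at -0.59. The astrocyte markers moved with these lists, at -1.21 over 11 markers. Relative to the 9 markers outside the list the reactive list stood at -0.41 (-3.43 to 0.09). The glutamate list stood at 0.24 (-0.04 to 0.52) relative to the 7 markers outside it, and at 0.08 (-0.20 to 0.36) relative to all of the class's markers. In the same nuclei oligodendrocyte markers were at 2624 and 1514 CPM, oligodendrocyte precursor markers at 1246 and 1768 CPM and striatal projection neuron markers at 1345 and 1893 CPM. With at least 5770 counts per barcode the reactive list stood at -0.17 and the glutamate list at -0.24, and with clusters weighted alike at -0.45 and -0.41. Most control astrocyte-like nuclei came from cluster 37 (173 control and 7 mKO nuclei) and most mKO nuclei from cluster 36 (77 and 112). By the rule, Piezo2 (-4.32), Ccdc190 (-2.88), Cbs (-2.21), Celrr (-2.06) and Nr2e1 (-2.71) were lower, and Tacr1 (3.01), Npy (2.16), Il1rapl2 (1.53), Tafa1 (1.45), Igf1 (1.73) and Sorbs2os (1.85), none specific to astrocytes, were higher. With clusters weighted alike Npy stood at 1.39, Il1rapl2 at 0.85 and Tafa1 at 0.65, and Tafa1 was higher in 1 of 3 clusters. With at least 5770 counts per barcode Ccdc190 stood at -1.35, Cbs at -1.30, Celrr at -1.02, Nr2e1 at -1.80 and Myoc at -2.45.

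Oligodendrocyte-like nuclei of the mKO library numbered only 10, at a median of 6652.5 counts against 3309.5 in the 712 control nuclei. Myelin genes had a median of -0.14 over 20 members (-0.30 to 0.12), 12 below 0, with Fa2h at -0.70, Trf at -0.57, Aspa at -0.49 and Mbp, myelin basic protein, at -0.25. The 15 oligodendrocyte markers stood at the same level, -0.14. Relative to all of them the list stood at -0.01 (-0.17 to 0.26), with 9 members above 0 and 11 below. Relative to the 4 markers outside the list, at -0.70, it stood at 0.56 (0.40 to 0.82). With the libraries clustered separately it was -2.64. Disease-associated oligodendrocyte genes had a median of -0.66 over 15 members (-1.38 to 0.09), with Il33 at -1.07, Apod at -1.05 and Stat3 at 261 and 2 counts (-1.75; -5.12 to -0.20). In that list 6 members had a count of 0, and with these at 3 counts its median was 0.36. By the rule, Tnr (3.50), Ctps (3.60), Ppfibp1 (3.64), Frmd4a (2.65), Pdzrn3 (2.80) and Ust (2.51) were higher, at 1.42 to 2.84 with at least 5770 counts per barcode. Of these 6, only Ctps was specific to the class, and in the same nuclei precursor markers were at 740 and 1427 CPM, excitatory neuron markers at 486 and 1014 CPM and striatal projection neuron markers at 239 and 613 CPM. Piezo2 (-2.48), Anln (-1.68) and Prr5l (-1.10) were lower, while Klhl24 and Cxxc5 gave 216 and 214 control counts and 0 mKO counts.

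Blood-brain barrier genes in endothelial-like nuclei had a median of -1.16 over 18 members (-1.37 to -0.99), 17 below 0, with Tek at -1.77, Pecam1 at -1.61, Flt1 at -1.37 and the transporter Slco1a4 at -1.35. Endothelial activation genes had a median of -0.98 over 13 members (-2.30 to -0.14), 11 below 0, with Vcam1, a leukocyte adhesion molecule, at -2.80 (-3.38 to -2.28), Icam1 at -2.30, Vwf at -1.94 and Lrg1 at 9 counts and 0. The median total count of endothelial-like nuclei was 4214 in the control library and 11165.5 in the mKO library. In these nuclei fibroblast markers were at 842 CPM in the control and 182 CPM in the mKO library. Rgs5 and Vtn, fixed markers of pericytes and smooth muscle, were among the leading genes of their cluster. The lower activation genes therefore cannot be assigned to endothelial cells alone. The endothelial markers stood at -1.37 over 11 markers. Relative to the 4 markers outside it the barrier list stood at 0.16 (0.05 to 0.47), and relative to all 11 at 0.07 (-0.09 to 0.33). The activation list, which held none of the markers, stood at 0.03 relative to them. With nuclei weighted equally they stood at -0.44 and -0.52. By the rule, the haemoglobin genes Hbb-bs (-5.89), Hba-a2 (-5.59) and Hba-a1 (-5.10), the smooth muscle genes Acta2 (-5.47) and Tagln (-5.32) and Cytl1 (37 counts and 0) were lower. Avp (3.31), Fndc5 (2.32), Slc6a7 (2.06), Slc30a3 (2.02), Mir124a-1hg (2.01) and Tmem181a (1.80) were higher. Of these 6, only Avp met the rule for specific, which compares mean levels of the named classes. Over all kept nuclei Avp gave 388 control and 493 mKO counts, and only 4 and 103 of them lay in endothelial-like nuclei. It therefore cannot be assigned to endothelial cells. In the same nuclei excitatory neuron markers were at 1816 and 2560 CPM and striatal projection neuron markers at 1074 and 1303 CPM. Oligodendrocyte markers were at 2488 and 3121 CPM.

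The last comparison concerned communication between cell classes, measured as the product of ligand and receptor levels, which does not measure signalling. Over 49 of 60 fixed pairs the median log2 ratio of products was -0.33 (-0.76 to -0.18), with 39 below 0 and 10 above. All 20 pairs with microglia as sender or receiver lay below 0, with a median of -0.64 (-1.20 to -0.24). The markers of microglia, astrocytes and endothelial cells were lower in the same nuclei, at -0.47, -1.21 and -1.37, and the products were not corrected for this. Among the microglia pairs Tgfb1 to Tgfbr1 within microglia-like nuclei stood at -1.45 and neuronal Cx3cl1 to microglial Cx3cr1 at -0.62. Astrocyte Csf1 to microglial Csf1r, the receptor microglia need for survival, stood at -1.37. Neuronal Il34 and oligodendrocyte Csf1 to the same receptor both stood at -0.24. Astrocyte Csf1 itself was at -1.06, beside the -1.21 of the astrocyte markers. Astrocyte Vegfa to endothelial Flt1 stood at -2.44, and Angpt1 to Tek at -2.92. The 12 pairs between neurons had a median of 0.02 (-0.11 to 0.15), 6 on each side of 0, and included Bdnf to Ntrk2 at 0.15 and Nrg3 to Erbb4 at -0.18. With at least 5770 counts per barcode the median over pairs was -0.03.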

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

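No single value met the rules for a closer look; 3 patterns are weighed here because a biologist would want to follow them up. The tests of the matched total count, of the unnamed clusters, of the microglial lists relative to the markers and of the cluster mix were chosen only after the results were seen, and the set of genes shifted alike was itself drawn up from the values. The test of the microglial lists was first written as 1 and was divided into the interferon-stimulated list and the others once their values were known.

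The 4 glia-like classes together were 10.4% of the control library and 2.40% of the mKO library, a log2 ratio of -2.12, or -0.52 with the 9 unnamed clusters closest to them. Barcodes of low total count missing from the mKO matrix cannot be told apart from a lower glial share: with both libraries at 5770 counts or more the ratio was -0.67 (-0.85 to -0.48) in the named clusters, -0.12 (-0.20 to -0.04) with the unnamed ones, and -0.00034 (-0.088 to 0.087) under the stricter filter on nuclei. Less glial RNA in the mKO library as a whole also cannot be told apart from no such loss, since the median of 64 glial markers over all kept nuclei was -0.21 (-0.32 to -0.10), which met both the bound written for it and the bound written against it; leaving it open was settled once the value was known. The pooled median includes the control barcodes under 5770 counts, which the mKO matrix lacks, so it is not independent of those missing barcodes. It also covers unlike classes. By class it was -0.51 (-0.59 to -0.23) for oligodendrocyte and -0.29 (-0.68 to -0.08) for precursor markers. For astrocyte markers it was -0.10 (-0.33 to -0.07), and for microglia markers -0.08 (-0.28 to 0.17). An effect of microglial cGAS deletion on glial numbers, a difference between the pooled tissues and a difference in nucleus recovery stay open and untested, as the design has 1 library per group.

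Interferon-stimulated genes were lower in mKO microglia-like nuclei. The medians of the other microglial lists were below 0 too. Intervals lay below 0 for the cGAS-STING, homeostatic, phagocytosis and cytokine lists. They held 0 for the disease-associated, antigen presentation, complement and DNA damage lists. For the interferon-stimulated list the median relative to the microglia markers was -0.57 (-1.06 to -0.02; 8 members), which argues against a smaller share of microglial RNA in mixed barcodes as the whole cause, by a narrow margin and by the definition of specific tried after the first one left 1 member. By cluster it was -0.78 in cluster 23, -1.48 in cluster 53 and 0.10 in cluster 39, and in the unnamed clusters 3 and 51 it was -0.15 and 0.49. For the 5 other lists with at least 3 specific members such a share cannot be told apart from a change within microglia: their medians relative to markers outside each list ran from 0.04 to 0.32 and all 5 intervals held 0, but only 3 of these intervals left out the value as measured; the cGAS-STING, antigen presentation and DNA damage lists, with 2, 2 and 0 specific members, were not tested. A lower interferon response after cGAS deletion is a hypothesis that these libraries leave open.

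Of 5876 genes, 24 differed by at least 0.3 in 1 direction in all 4 large neuron-like classes, 20 of them higher in the mKO library. With excitatory clusters weighted alike the median size of the shift was 1.02 times that measured. Genes entered the set by shifting in all 4 classes, which already disfavours genes moved by the cluster mix within 1 class. The test could therefore hardly have found a different mix of neuron clusters, and no conclusion on it is drawn. A genetic difference between the pools in linked stretches of the genome may contribute, but could not be decided: 2 neighbouring pairs were found, where random sets gave a median of 0 and a central range of 0 to 2. The genotype is confounded with the pool, so an effect of cGAS deletion in microglia on neurons stays open and untested.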

How the results depend on the processing

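The matched total, cluster 23 alone, the unnamed clusters (those with microglia markers among their leading genes and those closest to a glial class) and the ratios relative to markers, by both definitions of specific and both sets of markers, were tests chosen only after the results were seen. No paired analysis was possible because each group has 1 library and no result comes from a test. The 27 results had 352 alternative values, of which 246 lay within the interval of the value as reported, 83 moved outside it and 23 turned in sign from a value whose interval excluded 0. Counting values whose interval held 0 as well, 55 had the opposite sign. The interferon-stimulated list was negative in all 16 of its alternatives (-1.10 to -0.24), the cGAS-STING list in all 13 (-0.92 to -0.13), the reactive astrocyte list in all 14 (-1.68 to -0.17) and the ligand-receptor median in all 11 (-0.95 to -0.030); the separate clusters named in the report were not among these alternatives, apart from cluster 23. Cgas, DNA damage, GABA signalling, immediate early genes and amyloid processing stayed within their intervals in all their alternatives, where Cgas was above 0 in 1 of 12. The cause of the moves below was not tested. Thinning to 2000 counts left out no nucleus, since every total was higher. Clustering each library separately gave no microglia-like nuclei in the mKO library, so these results have no value there. The oligodendrocyte lists rest on 10 mKO nuclei. The share of oligodendrocyte-like nuclei, -5.83 as reported, and that of the 4 glia-like classes, -2.12, moved under each of their 7 and 6 alternatives. With these alternatives applied singly, both shares stayed negative. They were -0.14 and -0.49 with the stricter filter on nuclei, -1.67 and -1.36 without doublet removal, -1.01 and -0.52 at leiden resolution 0.5, -0.17 and -1.26 with libraries clustered separately, -2.24 and -0.67 at the matched lowest total, and -0.20 and -0.52 with the closest unnamed clusters. The -0.20 rests on cluster 3, which the microglia alternative counts too, and was -0.92 without the closest clusters that have microglia markers. Some combined alternatives turned the oligodendrocyte-like share. At the matched lowest total it was 0.17 (0.07 to 0.26) with the stricter filter and 2.81 (2.48 to 3.17) with libraries clustered separately. At that total it stayed negative without doublet removal (-0.52) and at leiden resolution 0.5 (-0.46). With libraries clustered separately and the closest unnamed clusters it was 0.20 (0.11 to 0.30) over all kept nuclei. The 2.81 came from 80 control and 565 mKO nuclei whose myelin level differed, as given above. At leiden resolution 0.5 the microglia-like share was 0.26, complement 0.047, phagocytosis -0.18 and myelin -0.88. At the matched lowest total the microglia-like share was -0.61, interferon-stimulated genes -0.43, homeostatic 0.016, disease-associated 0.18, antigen presentation 0.24, complement 0.045, phagocytosis -0.0051, reactive astrocyte -0.17 and ligand-receptor pairs -0.030. With the unnamed clusters that have microglia markers the share was 0.24, complement 0.052 and phagocytosis -0.16. Thinned to 2000 counts, interferon-stimulated genes were -0.99, homeostatic -0.69, disease-associated -0.68, cytokine and NF-kB -0.88, complement -0.99, phagocytosis -0.78, disease-associated oligodendrocyte 0.54 and ligand-receptor pairs -0.81. With nuclei weighted equally, interferon-stimulated genes were -1.10, homeostatic -0.70, disease-associated -0.65, cytokine and NF-kB -0.98, antigen presentation -0.72, phagocytosis -0.89 and ligand-receptor pairs -0.95. In cluster 23, interferon-stimulated genes were -0.24, homeostatic 0.12, disease-associated 0.20, cytokine and NF-kB -0.0077, antigen presentation 0.25, complement 0.076 and phagocytosis 0.071. Over the whole library relative to microglia markers, interferon-stimulated genes were -0.27, homeostatic 0.24, disease-associated 0.35, complement 0.23 and phagocytosis -0.12. Relative to the class's own markers outside the list, homeostatic genes were 0.15, disease-associated 0.32, cytokine and NF-kB 0.055, complement 0.23, phagocytosis 0.041, reactive astrocyte -0.41, astrocyte glutamate 0.24, blood-brain barrier 0.16, endothelial activation 0.028 and myelin 0.56. Relative to all of those markers, homeostatic genes were 0.14, disease-associated 0.32, cytokine and NF-kB 0.055, complement 0.22, phagocytosis 0.033, reactive astrocyte -0.39, astrocyte glutamate 0.083, blood-brain barrier 0.073, endothelial activation 0.028 and myelin -0.011, the last within its interval. By the definition of specific that was tried first, homeostatic genes were 0.21, phagocytosis 0.020, astrocyte glutamate 0.085, blood-brain barrier 0.21, endothelial activation 0.48 and myelin 0.52. With clusters weighted alike, complement was 0.039, reactive astrocyte -0.45 and ligand-receptor pairs -0.13. With libraries clustered separately, excitatory synapse was -0.041, MEF2C-linked -0.0099, myelin -2.64 and disease-associated oligodendrocyte -1.64. With TMM factors, excitatory synapse was -0.062, presynaptic -0.039, MEF2C-linked -0.072 and myelin -0.43. Myelin was -0.79 with the stricter filter on nuclei, -1.29 without doublet removal and -0.38 relative to all genes of the class.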

Other observations

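The level of Cgas in neurons, taken from excitatory neuron-like nuclei, was chosen as a test before its result was seen. That test was narrowed from RNA of all other cells to RNA of neurons after, and the test of Cgas RNA from other cells was chosen after. The other values here were picked out after the data were seen and were not tested.

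Interferon-stimulated genes were also lower outside microglia-like nuclei in the mKO library. In endothelial-like nuclei the median log2 ratio was -0.90 over 48 members (-1.22 to -0.53), 43 below 0, and in astrocyte-like nuclei -0.68 over 18 members (-1.25 to -0.39), 16 below 0, where the markers of these classes stood at -1.37 and -1.21. With at least 5770 counts per barcode the list stood at -0.79 and -0.20 in these classes, and with nuclei weighted equally at -0.28 and -1.02. In neurons the list stood at 0.07 in both excitatory and inhibitory neuron-like nuclei, over 6 and 7 members, and at 0.46 over 5 members in striatal projection neuron-like nuclei, with intervals that held 0. Immediate early genes, at -0.24 in excitatory neuron-like nuclei, stood at -0.05 in inhibitory, 0.03 in other excitatory, 0.02 in striatal and 0.23 in dentate granule neuron-like nuclei; the differences between classes were not tested. Cholesterol synthesis genes stood at -0.47 in astrocyte-like and at 0.55 over 18 members in endothelial-like nuclei, 16 of them above 0; with clusters weighted alike the astrocyte value was -0.08, and with nuclei weighted equally the endothelial value was 0.21. In the endothelial-like nuclei, markers of the class were at 4493 CPM in the control and 1747 CPM in the mKO library, excitatory neuron markers at 1816 and 2560 CPM and oligodendrocyte markers at 2488 and 3121 CPM. Fibroblast markers there were at 842 and 182 CPM.

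Among the genes shifted alike in all 4 large neuron-like classes, named here after their values were seen, Hspa5 stood at 0.43 to 0.63, Hsp90b1 at 0.35 to 0.45 and Calr at 0.31 to 0.40; all 3 code for chaperones, and no list of chaperones of their kind was tested. Scg2, a granin of secretory vesicles, Nptx1, a synaptic pentraxin, and Ube3a, a ubiquitin ligase, were also higher in all 4, with smallest ratios of 0.39, 0.41 and 0.31.

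Growth hormone RNA was among the leading genes of the microglia-like cluster 23, and over all kept nuclei Gh gave 1326 control and 27 mKO counts (-5.28; -5.92 to -4.76). Other pituitary hormone genes were lower too, with Prl at 93 and 19 counts and Pomc at 442 and 183, while Tshb gave 85 and 82. Haemoglobin RNA was lower in the mKO library, with Hbb-bs at 440 and 47 counts and Hba-a1 at 414 and 122.

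Cgas counts in mKO microglia-like nuclei may come from other cells. RNA of cortical and hippocampal excitatory neurons alone would put Cgas at or below the level in their nuclei. It was 3.29 times that level (1.47 to 6.03) in the mKO library and 6.23 times (4.13 to 9.05) in the control library. This argues against RNA of these neurons as the whole source. Other neuron-like classes were not in the test. In the mKO library dentate granule neuron-like nuclei had Cgas at 1.76 CPM (0.48 to 4.50), which overlaps the microglia-like interval of 1.94 to 7.45. Inhibitory, other excitatory and striatal neuron-like nuclei had upper bounds of 1.48, 1.66 and 1.32 CPM. RNA of other cells cannot be told apart from microglial RNA at this depth, since Cgas was 1.46 times (0.53 to 4.07) its level in endothelial-like nuclei of the mKO library, where it gave 9 counts. Whether the counts come from microglia that kept the gene or from transcripts of the deleted allele was not tested.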
